A study of Homo sapiens with 12 samples.

How the data were processed

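Transcripts were measured in 12 cultures of MA-2, a human melanoma cell line, with 1 one-colour (Cy3) Agilent whole human genome array per culture. The cells had been transfected with 75 nM of a precursor of miR-214, a microRNA, or with a control precursor, and were collected 48 h or 72 h later, per the labels. Each of the 4 groups had 3 arrays, which the labels describe as biological replicates, and the labels' protocols state a minimum RNA integrity number for all samples. The replicate number in the labels also named the slide and the scan day. Each slide carried all 4 groups, always in the same 4 positions, so position on the slide and group cannot be told apart.

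The scanner files hold, per the file headers, the processed signal of each spot, an intensity on a linear scale that Agilent Feature Extraction 10.5.1.1 made by subtracting background and removing trends across the array. Those intensities were not normalized between arrays, per the file headers. The same deposited files give the raw mean intensity of each spot and the median intensity of its local background. The deposited series table holds 33152 probes on a linear intensity scale. The order of its values within each array was that of the processed signal (Spearman rho of at least 0.999997 on every array), and all arrays shared 1 largest value, as quantile normalization gives. No header or label states how the authors normalized or filtered that table, so it served only as an alternative.

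Every array had 43376 spots that were not controls, on 41000 probes. No spot was saturated (0 on the 12 arrays), and between 59 and 152 outlier spots per array were left out. Between 64.1% and 80.9% of the spots were well above background, per the file headers' own call. For arrays the number of samples limits the precision. Probes were named through the given gene table (assembly GRCh38.p14, used for names only): 23958 probes matched on their own accession, 2496 on the symbol, 985 on an older symbol and 338 on another accession, and 13223 kept the name in the file. Probe positions are those of the files, on hg18.

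The log2 processed signal of each array was shifted by its 75th percentile. A probe was kept where it was well above background on all 3 arrays of at least 1 group, and the brightest kept probe stood for its gene, which left 21181 genes. A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 (R 4.3.3, the data.table package 1.17.8), with moderated variances. The 6 contrasts were the miR-214 precursor against control at 48 h, at 72 h and averaged over both times, the difference between these effects, and 72 h against 48 h in each transfection. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Intervals are 95% intervals of the same fit, which does not use the pairing of arrays by replicate number. Their median half-width at 48 h and at 72 h was 0.686, against 0.483 with the replicate number as a block.

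The same fit with the replicate number as a block was an alternative. The numbers paired the samples: arrays of different groups with the same number deviated from their group means together (correlation across genes 0.329 to 0.830 over 18 pairs, median 0.525). Those with different numbers mostly did not (median -0.280 over 36 pairs, highest 0.400), and centring on group means itself lowers these values. This was decided before the calls of both fits were compared. The slide and the scan day as blocks give the same model as the replicate number.

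Gene lists were tested with camera in limma, at its preset correlation of 0.01 between genes and again with an estimated correlation (statmod 1.5.0), for lists with at least 5 measured genes, adjusted over the 26 lists in each contrast. The lists held a panel of genes chosen for the study's question, 48 genes reported as targets of miR-214, G1/S and replication genes, G2/M and mitosis genes, replication-dependent histones, nuclear oxidative phosphorylation (OXPHOS) genes, and ribosomal proteins. Others held the interferon response, NF-kB and inflammation, the unfolded protein response, heat shock, p53 targets, MAPK feedback, TGF-beta and BMP signalling, Wnt and Hedgehog signalling, hypoxia and glycolysis, cholesterol synthesis, and the microRNA machinery. The rest were collagens and matrix, integrins and adhesion, EMT and invasion, melanocyte and MITF genes, and markers of fibroblasts, keratinocytes, endothelial cells and leukocytes. The panel listed 13 genes, of which 11 were measured: DNM3OS had no probe and CDH1 did not pass the filter.

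Genes were to be named by a rule: per comparison the called genes with the largest rises and falls whose groups did not overlap, the panel, and up to 4 members of each list with the smallest p. The design, the rule, the lists and the alternatives were fixed before the data were examined. The fit without the block called no gene (0 in all 6 contrasts), so after the values were seen the rule was applied to the calls with the replicate block between 48 h and 72 h, and genes of smallest p in the blocked fit were named for the miR-214 comparisons. Added after the data were seen were fits on slides 1 and 2 alone, the blocked fit with other scalings, filters and left-out arrays, an exchange of labels on slide 3, 2 more lists (targets of YAP and TAZ, and quiescence and FOXO targets), and fry, a test of whether the genes of a list move together in 1 direction.

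The alternatives tried were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter over all 12 arrays, the mean of a gene's probes, only the compared groups in the fit, an intensity trend with a robust prior, the blocks, the series table, and each array left out in turn. A test of genes with a miR-214 seed site, fixed beforehand, was not run, since no 3′ UTR sequence was at hand. The scripts were tested on simulated data with 21083 genes, 50 of them changed per fold size. Without the block, 30, 29, 24 and 29 of 50 genes changed 4-fold were recovered for the miR-214 effect at 48 h, at 72 h, and for time in control and in miR-214 cells, with 0 unchanged genes called. With the block these were 48, 42, 45 and 45 of 50, with 6, 5, 6 and 6 unchanged genes called. At 2-fold, the fit without the block recovered 0, 1, 0 and 3 of 50, and that with the block 22, 18, 17 and 13. The simulation drew noise independently between genes, with 1 spread per gene on all slides. On the real arrays the miR-214 differences at 48 h had an SD across genes of 0.57, 0.35 and 0.83 by slide. These counts are therefore not recovery or error rates of the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.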

Results

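The series asked how raising miR-214, a microRNA studied in melanoma progression, changes the transcripts of MA-2 melanoma cells. MA-2 cultures carrying a miR-214 precursor or a control precursor were profiled 48 h and 72 h after transfection, with 3 arrays in each of the 4 groups. Of 43376 spots per array, between 27803 (control, 48 h, replicate 2) and 35085 (miR-214, 72 h, replicate 3) were well above background. After the filter on dim probes, 21181 genes were compared. The array does not measure the precursor itself.

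The arrays of slide 3 stood apart from the others. The first principal component held 47.8% of the variance and set the slide 3 arrays of both 48 h groups and of the miR-214 cells at 72 h apart from all others. The second component held 16.5%. In 6 of 6 pairs of the same slide and time the miR-214 array had the higher first component, a difference that was not tested. Its size was uneven. At 48 h the miR-214 and control values were -8.4 and -9.7 on slide 1, -28.5 and -29.8 on slide 2, and 118.8 and 81.2 on slide 3. At 72 h they were -29.9 and -39.9, -44.0 and -51.3, and 43.6 and -2.1. Position on the slide parts these arrays in the same way. On slide 3, against slides 1 and 2, the median of the G1/S and replication genes was higher by 0.47 on the log2 scale and that of the G2/M and mitosis genes by 0.44. The median of 6 endothelial markers was higher by 0.69. Medians were lower there for fibroblast markers (-0.44), integrins and adhesion (-0.43), replication-dependent histones (-0.36) and collagens and matrix (-0.29). The within-slide differences between miR-214 and control cells at 48 h had an SD across genes of 0.57, 0.35 and 0.83 on slides 1, 2 and 3. Signal toward the 5′ end of transcripts, relative to the 3′ end, was compared over 2363 probe pairs, each centred on its all-array mean. The medians were lower on all 4 arrays of slide 3 (-0.18 to -0.06, log2) than on the other 8 (0.04 to 0.15). They are deviations from that mean, so their signs follow in part from the centring. Distances between the probes of a pair are genomic.

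**Figure D1:**
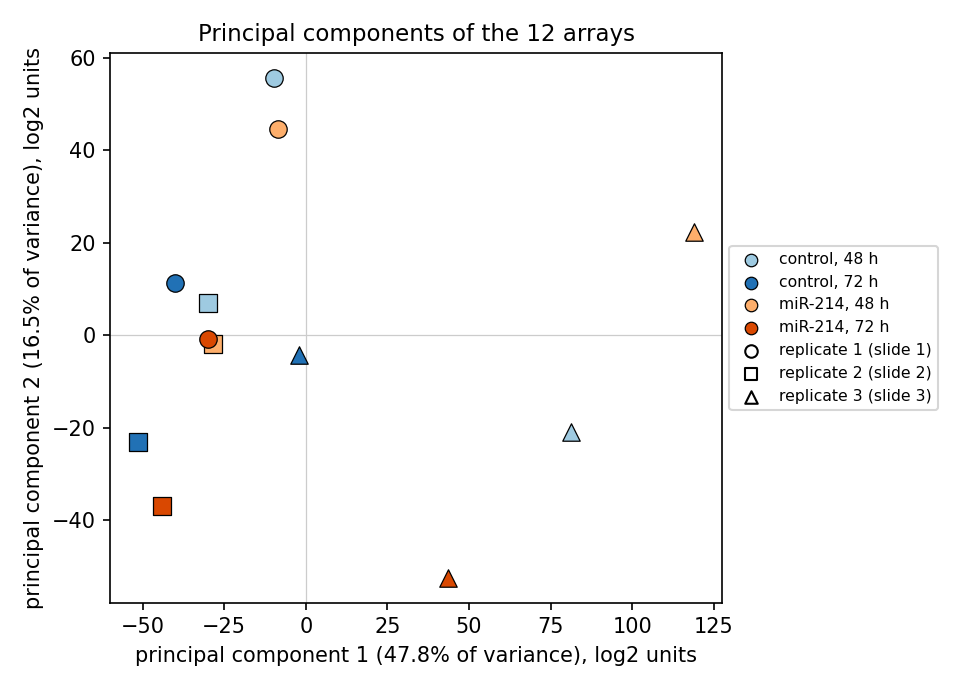
First and second principal components of the 12 arrays, in log2 units (47.8% and 16.5% of the variance), with colour for group and marker shape for replicate number, which is also the slide. The slide 3 triangles lie to the right of all other arrays, the control array at 72 h by the smallest distance, and arrays of the same slide and time lie close together on slides 1 and 2.

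At 48 h, transcripts of the genes the study is about did not differ between miR-214 and control cells by more than the spread between replicates. TFAP2C, which encodes the transcription factor AP-2 gamma and is a reported target of miR-214, stood at 1.33 ± 0.38 in control and 0.73 ± 0.72 in miR-214 cells (log2 relative to the array's 75th percentile, SD, n = 3). Its difference was -0.60 (95% interval -1.33 to 0.13), with -0.11, 0.11 and -1.80 on slides 1, 2 and 3. The intervals given for panel genes ignore the pairing by replicate number. With the block, the smallest limma adjusted p of any gene at 48 h was 0.64. ITGA3, the integrin alpha 3 subunit, differed by -0.69 (-1.79 to 0.40) and ITGA5, integrin alpha 5, by -0.52 (-1.77 to 0.73), again carried by slide 3 (-1.66 and -1.75). Without the miR-214 array of replicate 3, TFAP2C differed by -0.19, ITGA3 by -0.05 and ITGA5 by 0.29. ALCAM, a cell adhesion molecule, differed by 0.12 (-0.41 to 0.65). Of the other panel genes, ITGAV, MET, MCAM, MITF, DCBLD2 and the dim TFAP2A lay between -0.21 and 0.00. The TFAP2C probe lies on chromosome 20 (54647053 to 54647112, hg18), the ITGA3 probe on chromosome 17 (45522364 to 45522423) and the ITGA5 probe on chromosome 12 (53075923 to 53075982).

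Among gene groups at 48 h, nuclear OXPHOS genes and replication-dependent histones were higher in miR-214 cells by the list test, and slide 3 held both differences. The OXPHOS list, subunits of the respiratory chain and its assembly, had a median of 0.22 with 25 of 32 genes above 0 (camera, adjusted p = 0.00052, and adjusted p = 0.911 with an estimated correlation). Its medians were -0.06, 0.01 and 0.71 on slides 1, 2 and 3; NDUFB5 differed by 0.58, COX6C by 0.75, COX7B by 0.47 and NDUFA1 by 0.79. The histone list had a median of 0.28 with 15 of 16 genes above 0 (adjusted p = 0.0108, and adjusted p = 0.911 with an estimated correlation) and slide medians of -0.10, 0.04 and 0.95. H4C2 differed by 0.46, H4C8 by 0.43, H1-3 by 0.36 and H4C3 by 0.32. Both lists had an adjusted p = 0.939 on slides 1 and 2 alone. No member of either list was called, and 0 were called when adjusted over the list alone. Without the control or the miR-214 array of replicate 3, the adjusted p was 0.116 and 0.234 for OXPHOS and 0.876 and 0.137 for histones. The histone call was also lost without the control array of replicate 2 (0.094) or the miR-214 array of replicate 1 (0.273). The 47 measured reported targets of miR-214 had a median of -0.05 (adjusted p = 0.577). Among them CTNNB1, which encodes beta-catenin, differed by -1.61 (-0.94, 0.03 and -3.91 by slide), ARL2 by -0.44, ING4 by -0.35 and NRAS by 0.47, none called. The other 24 lists, the reported targets among them, had adjusted p from 0.1 (leukocyte markers, median -0.31) to 0.994 (G1/S, EMT, ribosomal protein, NF-kB and endothelial lists).

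limma called 0 of 21181 genes at 48 h, and the blocked fit and all other alternatives also gave 0. At an unadjusted p under 0.05 there were 483 genes (1500 with the block), where chance gives 1059. In 916 genes (4.32%) the groups did not overlap, where chance gives 10% for unpaired arrays; replicate number paired these arrays, and the chance share under pairing was not computed. Differences beyond 1 on the log2 scale lay outside the 95% interval for 57.0% of genes (74.5% with the block). Genes of smallest p in the blocked fit were named after their values were seen, and all had an adjusted p = 0.64. They included ZMAT3, a p53 target that encodes a zinc finger protein (1.34, SE 0.24; 1.27, 0.83 and 1.91 by slide) and RTN4 (0.65). On the lower side were GPAT2 (-0.85), OLFML2B (-0.81), GLP2R (-0.80) and ZBTB22 (-0.69).

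**Figure D2:**
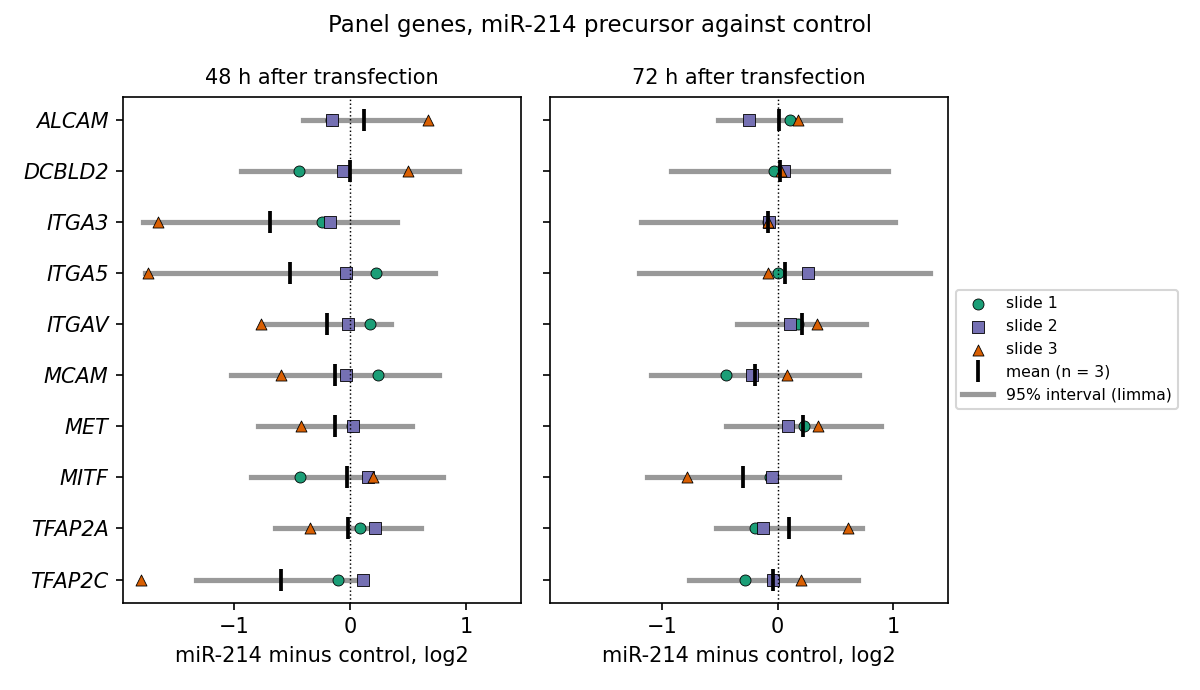
Difference between miR-214 and control cells (log2, horizontal axis) for 10 panel genes at 48 h (left) and 72 h (right). Markers are within-slide differences and bars the means (n = 3 slides). Grey lines are the 95% intervals of the limma fit without the block, all of which include 0. At 48 h the slide 3 triangles of TFAP2C, ITGA3 and ITGA5 lie at or below -1.66.

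At 72 h the panel genes again lay within the spread between replicates, and closer to 0. TFAP2C differed by -0.04 (95% interval -0.77 to 0.69), from 1.13 ± 0.22 in control to 1.09 ± 0.12 in miR-214 cells (log2, SD, n = 3). ALCAM differed by 0.01 (-0.51 to 0.54), ITGA3 by -0.08 (-1.18 to 1.01) and ITGA5 by 0.06 (-1.19 to 1.31). MET, a receptor tyrosine kinase, differed by 0.22, ITGAV by 0.21, MCAM by -0.19 and MITF, the melanocyte master regulator, by -0.30. The reported targets of miR-214 had a median of 0.03 (adjusted p = 0.919). Replication-dependent histones had a median of -0.13 with 12 of 16 genes below 0; their adjusted p was 0.0555, and 0.0497 with the replicate block. With an estimated correlation and the block that p was 0.967. H4C2 differed by -0.61, H1-3 by -0.66 and H4C3 by -0.53. G2/M genes and TGF-beta and BMP genes had medians of 0.12 and 0.14 (adjusted p = 0.296 for both) and collagens and matrix of 0.10 (0.377). None of the 26 lists passed, with adjusted p up to 0.983.

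limma called 0 genes at 72 h, in the blocked fit as well (unadjusted p under 0.05: 116 and 815). Leaving out the miR-214 array at 72 h of replicate 3 in the blocked fit gave 1 gene, and the other alternatives gave 0. In 1867 genes (8.81%) the groups did not overlap, where chance gives 10% for unpaired arrays, which these were not. The smallest blocked adjusted p, 0.18, was that of GSDMA, which encodes the pore-forming protein gasdermin A. It was not called, and was not well above background in any control array at 72 h. With the main processing it was at least 3.22-fold higher in the miR-214 arrays (n = 3). That bound compares group means and is not a confidence limit. Other genes of small p, named after their values were seen, were ZNF667 (1.81), ZNF19 (0.58), GPR78 (-1.25), C3AR1 (-1.15) and DDX6 (-0.82), all with a blocked adjusted p = 0.949. DDX6, a helicase of microRNA-mediated repression, differed by -0.52, -0.88 and -1.07 on slides 1, 2 and 3.

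Averaged over both times, no gene was called by limma in either fit (0; unadjusted 437, and 1926 with the block), and none of the 26 lists passed (adjusted p 0.082, for OXPHOS genes, to 0.968). The effect at 72 h minus that at 48 h also gave 0 genes (unadjusted 183, and 608 with the block), with 1 gene when the miR-214 array at 72 h of replicate 3 was left out of the blocked fit. Histones and OXPHOS genes differed between the times. All 16 histones had a lower effect at 72 h (median -0.36, camera adjusted p = 1.62e-05, and adjusted p = 0.822 with an estimated correlation), among them H4C2 (-1.07), H1-3 (-1.02) and H4C3 (-0.85). So did 27 of 32 OXPHOS genes (median -0.21, adjusted p = 0.001, and adjusted p = 0.822 with an estimated correlation), among them NDUFC1 (-1.11), COX6C (-0.78) and COX5A (-0.68). On slides 1 and 2 alone the adjusted p was 0.562 for histones and 0.642 for OXPHOS genes. Without the miR-214 array at 48 h of replicate 3 the OXPHOS value was 0.367. The other 24 lists had adjusted p from 0.333 to 0.790. Across genes, which are not independent replicates, the effects at 48 h and 72 h had a Pearson r of 0.157 and a Spearman rho of 0.212, with the same sign in 59.2% of genes. Within slides 1, 2 and 3 the r was 0.53, 0.18 and -0.25. It was -0.216 without the control array at 48 h of replicate 1, 0.529 without that of replicate 3, and -0.112 without the miR-214 array at 48 h of replicate 3.

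Between 48 h and 72 h, genes of cell division were lower at the later time in control cells, and collagen and matrix genes were higher as a list. All 35 measured G1/S and replication genes had a negative change (median -0.58; -0.61, -0.46 and -0.65 by slide; camera adjusted p = 1.80e-16, and adjusted p = 0.558 with an estimated correlation). So had 37 of 38 G2/M and mitosis genes (median -0.59; -0.77, -0.40 and -0.76 by slide; adjusted p = 3.31e-17). Both lists had an adjusted p = 0.558 with an estimated correlation, which with the block was 0.118 and 0.175. In the fit with the replicate block 5 members of each list fell, and 25 and 28 fell when adjusted over the list alone. They included RRM2, a subunit of ribonucleotide reductase (-1.21, SE 0.17, adjusted p = 0.0171), the cyclins CCNE2 (-1.22) and CCNA2 (-0.93), the transcription factor E2F1 (-1.04), and BIRC5, or survivin (-0.92). Collagen and matrix genes rose as a list (median 0.16, adjusted p = 0.0454; 0.644 with an estimated correlation), with the laminin LAMA5 at 1.07 and the fibrillin FBN1 at 1.06 called by the blocked fit and 6 members when adjusted over the list alone. FAP, a fibroblast marker, rose by 0.93 in the same cells. That list's call was lost without the control array of replicate 1 (0.126) or 3 (0.166) at 48 h and of replicate 1 (0.165) or 2 (0.210) at 72 h. Heat shock genes fell as a list (median -0.27, adjusted p = 0.0189, and adjusted p = 0.558 with an estimated correlation), with HSPA1A at -0.48 and HSP90AA1 at -0.68 not called; the small heat shock protein CRYAB, at 0.73, was not called either. Hypoxia and glycolysis (median -0.17), reported miR-214 targets (-0.19) and the unfolded protein response (-0.07) were lower and histones (0.32) higher, with adjusted p from 0.0454 to 0.0468. The estimated correlation gave an adjusted p of at least 0.558 for every list, and with the block the unfolded protein response (0.0503) and histones (0.078) did not pass. Hypoxia and reported target genes were both at 0.0854 with quantile normalization, and at 0.0725 and 0.059 with normexp. The remaining 18 lists had adjusted p from 0.0595 to 0.622.

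Of single genes, 344 were called in control cells with the replicate block, 222 higher and 122 lower at 72 h, of which 161 and 56 changed at least 2-fold. DKK1, a secreted inhibitor of Wnt signalling, had the largest fall among the named genes (-3.31, SE 0.24, adjusted p = 0.00407; -3.41, -2.83 and -3.68 by slide). Its probe lies on chromosome 10 (53746693 to 53746752, hg18). The keratin KRT80 changed by -2.66 (chromosome 12, 50849752 to 50849811), NIBAN1 by -1.66, ENC1, which encodes an actin-binding protein, by -1.64 (chromosome 5, 73960011 to 73960070) and LYPD1 by -1.64. RCAN2, a regulator of calcineurin, rose by 2.45 (SE 0.45, adjusted p = 0.0387). BPIFB1, SELENOP, which encodes the selenium carrier selenoprotein P, and TTC39A were not well above background on any control array at 48 h. With the main processing they were at least 3.49-fold, 2.21-fold and 2.62-fold higher at 72 h (n = 3). Over the alternatives their lowest fitted changes were 0.78, 0.41 and 0.55 (log2), below these bounds. Without the block limma called 0 genes (unadjusted 948, smallest adjusted p 0.908; 3702 unadjusted with the block), and on slides 1 and 2 alone or with normexp the blocked fit also called 0. With median centring the split was 148 higher and 141 lower. With 1 array left out the blocked count was 83, 70 and 84 (control, 48 h, replicates 1, 2 and 3), 5, 49 and 27 (control, 72 h), 188, 194 and 1292 (miR-214, 48 h), and 128, 130 and 136 (miR-214, 72 h). In 2062 genes (9.74%) the groups did not overlap, where chance gives 10% for unpaired arrays, which these were not.

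In miR-214 cells the division genes were lower at 72 h as well, and collagen and matrix genes were higher. G1/S genes had a median of -0.49 with 34 of 35 genes below 0 (-0.57, -0.44 and -0.70 by slide), and G2/M genes a median of -0.48 with 37 of 38 below 0 (-0.71, -0.38 and -0.47 by slide). The camera adjusted p was 2.19e-12 for both, 0.472 with an estimated correlation, and 0.176 and 0.184 with that and the block. In the blocked fit 8 and 5 members fell, and 21 and 23 when adjusted over the list alone. They included RRM2 (-1.23, SE 0.17, adjusted p = 0.0121), CLSPN (-1.22), E2F1 (-1.19), GINS2 (-0.92), CENPA (-1.08), CCNA2 (-0.96) and the mitotic kinase PLK1 (-0.88). Collagen and matrix genes rose as a list, with 28 of 37 above 0 (median 0.42; 0.36, 0.24 and 0.30 by slide; adjusted p = 0.000335). With an estimated correlation the adjusted p was 0.472. In the blocked fit 7 members rose and 11 rose and 1 fell when adjusted over the list alone. Examples were COL4A5, a basement membrane collagen (1.59), LAMA3 (1.20), the proteoglycan BGN (1.18), FBN1 (1.17) and LAMA5 (1.08), and the fibroblast marker FAP rose as well. Heat shock (median -0.30, adjusted p = 0.0123), microRNA machinery (-0.25, 0.028) and OXPHOS genes (-0.16, 0.028; 0.14, 0.04 and -0.64 by slide) were lower and melanocyte and MITF genes higher (0.36, 0.028). With an estimated correlation no list had an adjusted p below 0.401, and with the block the OXPHOS (0.0643) and melanocyte (0.0587) lists did not pass. AGO2, the slicing Argonaute, changed by -0.51 and was not called. The remaining 19 lists had adjusted p from 0.0511 to 0.831.

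**Figure D3:**
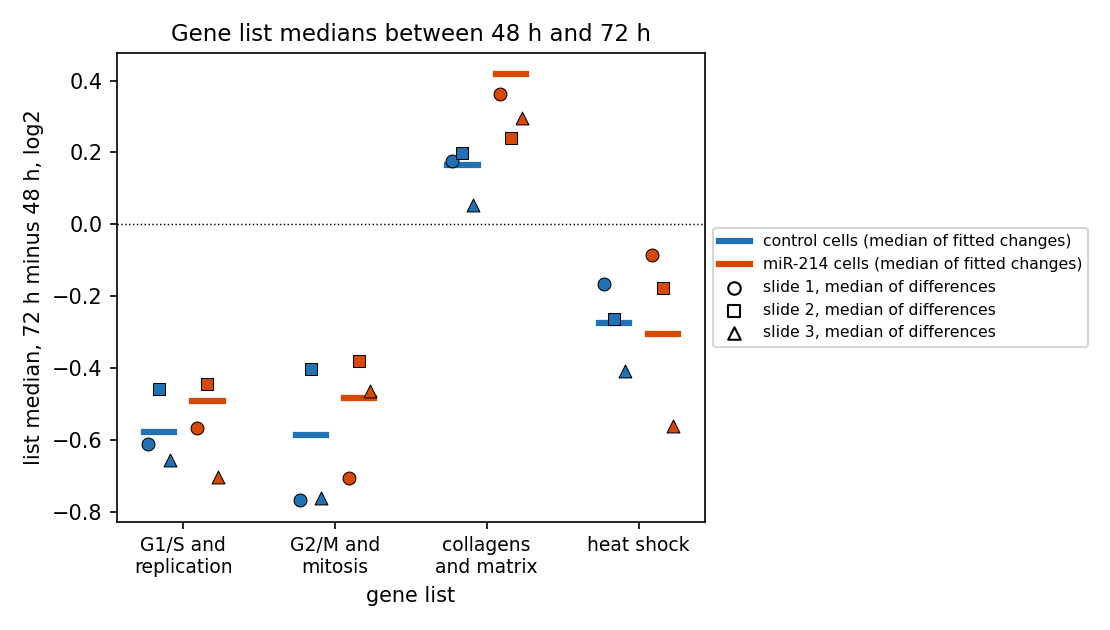
Median change of 4 gene lists between 48 h and 72 h (log2, vertical axis) in control (blue) and miR-214 cells (orange). Horizontal bars are medians of the fitted changes and markers the medians of within-slide differences (n = 3 slides); every marker of the G1/S, G2/M and heat shock lists lies below 0 and every marker of the collagen list above 0.

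The blocked fit called 716 genes in miR-214 cells, 508 higher and 208 lower at 72 h, of which 317 and 94 changed at least 2-fold. DKK1 changed by -3.36 (SE 0.24, adjusted p = 0.00284), IL7R, the interleukin 7 receptor, by -2.85, CALB2, or calretinin, by -2.64, the linker histone H1-1 by -2.27, and ENC1 by -1.90. BDKRB2, the bradykinin B2 receptor, rose by 3.10 (SE 0.29, adjusted p = 0.00473; 3.69, 2.24 and 3.36 by slide; chromosome 14, 95780094 to 95780153). BPIFB1, GSDMA and TAF7L were not well above background on any miR-214 array at 48 h. With the main processing they were at least 4.23-fold, 3.11-fold and 3.04-fold higher at 72 h (n = 3). Over the alternatives their lowest fitted changes were 0.85, 0.71 and 0.70 (log2), below these bounds. IL3RA, an interleukin 3 receptor subunit, was called higher and had no array above background at 48 h, so no fold is given. Without the block limma called 0 genes (unadjusted 1664, smallest adjusted p 0.608; 4301 unadjusted with the block), and on slides 1 and 2 alone or with normexp the blocked fit also called 0. With median centring the split was 327 higher and 219 lower. With 1 array left out the blocked count was 59, 491 and 397 (miR-214, 48 h, replicates 1, 2 and 3), 14, 148 and 29 (miR-214, 72 h), 638, 516 and 591 (control, 48 h), and 296, 366 and 557 (control, 72 h). In 2377 genes (11.2%) the groups did not overlap, where chance gives 10% for unpaired arrays, which these were not.

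**Figure D4:**
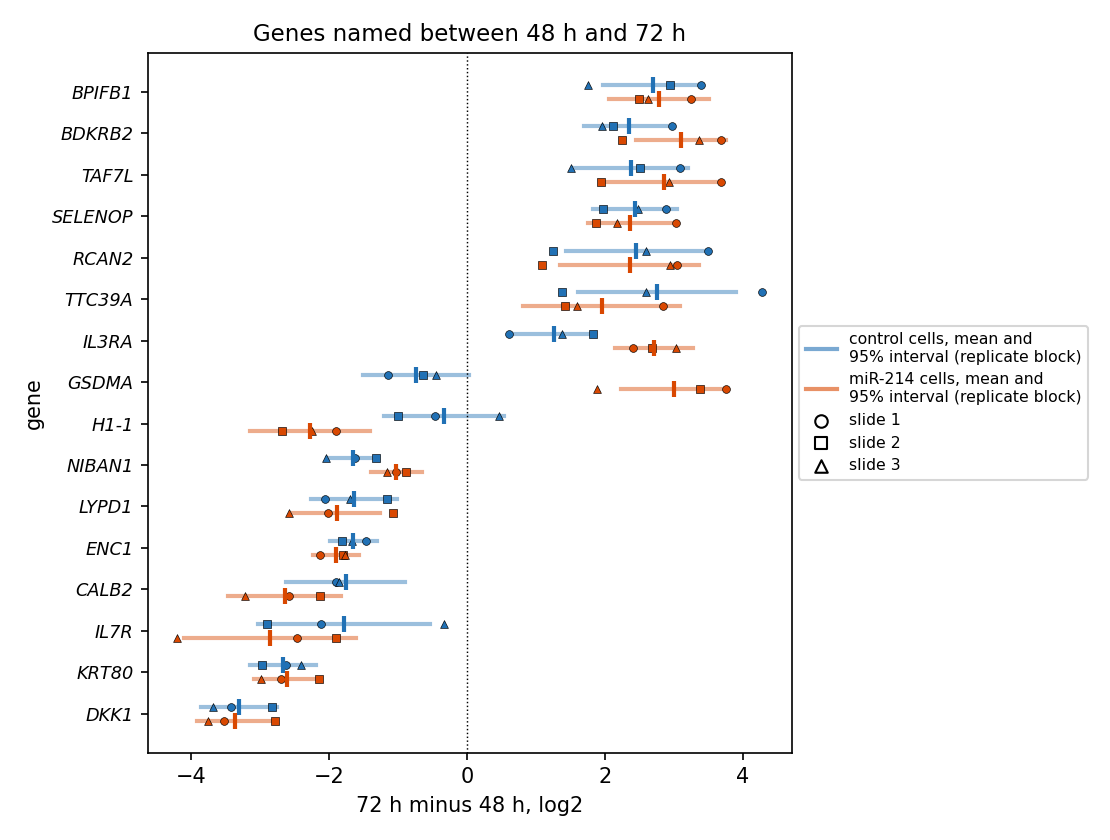
Change between 48 h and 72 h (log2, horizontal axis) of 16 genes with large changes in either time comparison, in control (blue) and miR-214 cells (orange). Markers are within-slide differences, vertical bars the means (n = 3 slides) and horizontal lines the 95% intervals of the fit with the replicate block; changes of genes below background at 48 h, such as BPIFB1, are fitted values and not folds.

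The time changes of both transfections overlapped: 274 genes were called in both, 185 higher and 89 lower, where independent lists of these sizes would share 5.32 and 1.20. No gene was called in opposite directions (0). DKK1, ENC1, BPIFB1 and RRM2 were among the 274. Both comparisons share no array, but they come from the same slides and from 1 fit with 1 variance per gene, so their calls are not independent. Position on the slide goes with time in both. A test of the difference between both time changes is the 72 h effect minus the 48 h effect, for which limma called 0 genes. GSDMA had the smallest blocked adjusted p of that difference (0.524); it was not above background on most arrays, so no size is given.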

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

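The tests of slides 1 and 2 alone, of members that move together, of 5′ signal and of dimmer hybridization on slide 3 were chosen after the results they measure were seen. Replication-dependent histones and nuclear OXPHOS genes stood out because their miR-214 effects at 48 h and 72 h differed in a test of the difference itself. At 48 h the histones had a median of 0.28 above control and at 72 h of -0.13, and all 16 had a lower effect at 72 h (median of the difference -0.36, camera adjusted p = 1.62e-05, and adjusted p = 0.822 with an estimated correlation). H2BC5 (-2.29), H4C2 (-1.07), H1-3 (-1.02) and H4C3 (-0.85) had large differences, none called. OXPHOS genes had medians of 0.22 and -0.02, and 27 of 32 had a lower effect at 72 h (median of the difference -0.21, adjusted p = 0.001, and adjusted p = 0.822 with an estimated correlation).

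For the histone and OXPHOS difference, the arrays of replicate 3 are a candidate explanation. On slides 1 and 2 alone the adjusted p was 0.562 for histones and 0.642 for OXPHOS genes, and fewer arrays also make that test weaker. With an estimated correlation between genes, which allows for members that move together, the smaller adjusted p of both lists was 0.822. A timed effect of miR-214 on these genes stays open as well, since neither test excludes it.

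The slide 3 arrays stood apart from the others, with division genes higher and integrins, histones and matrix genes lower. Dimmer hybridization of the whole slide was argued against, since 2 of the 4 arrays had more spots well above background than the median of the other 8 (31223). These were the 72 h arrays (35085 for miR-214 and 32130 for control cells). The 48 h arrays, furthest out on the first component, lay below that median (30229 for miR-214 and 31198 for control cells). For the 48 h arrays dimmer hybridization stays open. The linear fit of the spike-in controls had a lower R2 on some slide 3 arrays. It was 0.992 for control and for miR-214 cells at 48 h, and 0.991 for miR-214 cells at 72 h. Every other array, the slide 3 control at 72 h included, had at least 0.997. The lower values thus fell on the arrays that the first component set furthest apart, and their cause was not tested. Lower RNA integrity or shorter cDNA may contribute, since the highest centred 5′ minus 3′ median of slide 3 lay 0.101 below the lowest elsewhere. Pairs under 200 bases apart on the genome were parted the same way but less. Their centred medians were -0.0441 to -0.00494 on slide 3 and -0.00262 to 0.0266 on the other arrays. An exchange of the labels of both 48 h arrays of slide 3 would leave slide 3 apart as before, and bears only on differences within it, where the residual was 97.868% of that of the deposited labels, just past an arbitrary margin of 2% fixed beforehand; the same exchange gave 99.61% on slide 1 and 101.8% on slide 2, so an exchange stays open. With it limma called 0 genes at 48 h and averaged over both times (unadjusted 558 and 756, against 483 and 437 as deposited), the effects at 48 h and 72 h had an r of 0.37 across genes against 0.157, and the slide 3 differences at 48 h, such as those of OXPHOS genes (0.71), histones (0.95) and TFAP2C (-1.80), would by construction turn sign. RNA of another cell type, to be dropped if no marker median exceeded 1, was left open after the values were seen, because the highest marker median, 0.69 for 6 endothelial genes, had a bootstrap SD of 0.640 and so did not lie below 1 by more than its spread, and different growth of the cultures was not tested.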

How the results depend on the processing

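The fits on slides 1 and 2 alone, all alternatives of the blocked counts and those of the G1/S and G2/M lists were chosen after the data were seen. With the block, 3 list members at 48 h, 1 at 72 h and 4 averaged over both times were called when adjusted over the list alone, against 0 without it, and 102 and 109 between 48 h and 72 h in control and miR-214 cells, against 0 and 2. It changed no other call beyond those given here and in the report.

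Without the block, limma called 0 genes in all 6 contrasts under every alternative run, each array left out included. The replicate, slide and scan date blocks, which are 1 model, called 344 genes between 48 h and 72 h in control cells and 716 in miR-214 cells. Those blocked counts were 0 and 0 on slides 1 and 2 alone (unadjusted 4106 and 4100) and 0 and 0 with normexp (unadjusted 1809 and 2245). With no filter on dim probes they were 94 and 241, over more genes tested. With 1 array left out they lay between 5 (without the control array at 72 h of replicate 1) and 1292 (without the miR-214 array at 48 h of replicate 3) in control cells, and between 14 (without the miR-214 array at 72 h of replicate 1) and 638 (without the control array at 48 h of replicate 1) in miR-214 cells. Slides 1 and 2 alone hold fewer arrays; otherwise the cause was not tested.

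The G1/S and G2/M lists were lower at 72 h under all 23 alternatives for which camera was run on lists. Camera was not run on lists with the series table, the filter over all 12 arrays, the intensity trend, or only the compared groups in the fit. With the block it was run under quantile normalization, under median centring and on slides 1 and 2, but not with the other processing choices. Their adjusted p lay between 3.59e-19 and 0.558 for G1/S and between 4.06e-19 and 0.558 for G2/M in control cells. In miR-214 cells it lay between 6.05e-17 and 0.472 and between 1.01e-17 and 0.472. The highest values, 0.558 and 0.472, came with an estimated correlation, the only one of the alternatives run under which these lists did not pass.

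Of the 26 lists 2 passed at 48 h, 0 with an estimated correlation and 1, ribosomal proteins, on slides 1 and 2 alone with or without the block (1 each); with an array left out, 0 (control, replicate 3) to 7 (miR-214, replicate 2). At 72 h 0 passed, 3 with normexp and 1, histones, with quantile normalization, 1 with the mean of probes, 1 with the block, 1 with the block and quantile normalization or median centring, and 0 to 3 with an array left out (3 without the miR-214 array at 72 h of replicate 2). Averaged over both times 0 passed, 4 with normexp, 1 with no filter, and 0 to 4 with an array left out (4 without the miR-214 array at 48 h of replicate 2). The cause was not tested.

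The correlation of the effects at 48 h and 72 h, 0.157, was 0.417 with normexp and 0.409 on slides 1 and 2, and -0.216 to 0.529 with an array left out. Normexp moved the median of all genes at 72 h by 0.119, and with it TFAP2A (0.64) and ALCAM (0.43) moved by more than their spread. Some time changes shrank more with another scaling, background correction or choice of probes than with any array left out. In miR-214 cells CALB2 then reached -0.79 and IL7R -1.09, against -2.05 and -2.44 with an array left out. BDKRB2 reached 1.75 against 2.46 there, and RCAN2 1.11 against 2.16 in control cells. DKK1 stayed at -2.52 or beyond in both transfections. Of the named gene values, 625 stayed on their side of the threshold and within their spread, 27 moved, 20 passed it with the block and 0 reversed. Seed site tests were not run, and a fit of only the compared groups cannot be made for the averaged effect and its difference. Between 64.1% and 80.9% of spots were well above background, and for genes not well above background on any array of a compared group the text gives a bound or no fold. Such a bound compares group means, is not a confidence limit and holds for the main processing only.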

Other observations

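At 72 h against 48 h, single inflammatory, interferon, melanocyte and adhesion genes changed beside the division genes. The fry test, the YAP and TAZ and quiescence lists, and the tests of single slides and of position were chosen after the time changes were seen. In control cells the cytokines IL1A (0.91), IL1B (1.03) and CXCL2 (0.95) rose in the fit with the replicate block, as did the TGF-beta family member INHBA (1.29), the BMP target ID3 (1.14), the interferon-induced BST2 (1.48) and CAPN3, a melanocyte gene (1.55). NGFR, the nerve growth factor receptor of dedifferentiated melanoma cells, fell (-1.89), and so did the matrix protein THBS1 (-1.53), ANGPTL4 (-1.34), FZD8 (-0.91), NECTIN3 (-1.02) and TFAM (-0.78). In miR-214 cells IL1A (1.05), IL1B (1.04), ICAM1 (0.95), LIF (1.28), BST2 (2.06), CAPN3 (1.94), APOE (1.21) and CD68 (1.39) rose. There the chemokine CCL2 (-1.80), the YAP target CCN2 (-2.28), JUN (-1.57), SOX2 (-1.37), MMP1 (-0.93), EPHA4 (-1.63), KLF4 (-0.84) and NGFR (-1.86) fell. KLF4 and SOX2, which belong to no list, were named after their values were seen.

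By fry, which asks whether the genes of a list move together, inflammation genes had an adjusted p = 0.018 in control and 0.00509 in miR-214 cells (medians 0.07 and 0.15). The values were 0.0491 and 0.00509 for interferon genes (medians 0.08 and 0.17), 0.0491 and 0.0114 for melanocyte genes (0.26 and 0.36), 0.0491 and 0.01 for fibroblast markers (0.21 and 0.22), and 0.037 and 0.00941 for endothelial markers (-0.22 and -0.55). G1/S genes had 0.00175 and 0.0026, G2/M genes 0.00565 and 0.00509, and collagens 0.037 and 0.00509. Under median centring, quantile normalization and normexp, the G1/S and G2/M lists passed in both transfections (adjusted p up to 0.0203), and collagens and melanocyte genes in miR-214 cells (up to 0.0203 and 0.0416) but not in control cells. Reported miR-214 targets were lower by fry in control cells (adjusted p = 0.0103, and up to 0.029 under these scalings). In miR-214 cells their fry value was 0.102, and 0.0384 with quantile normalization. MicroRNA machinery genes were lower by fry in miR-214 cells (0.01, and up to 0.0203 under these scalings). In control cells their fry value was 0.0948, and 0.0459 with median centring. A test of the difference between both time changes passed for neither list. The camera adjusted p without the block was 0.488 for reported targets and 0.435 for microRNA machinery. With median centring inflammation genes had an adjusted p = 0.33 and 0.082 and interferon genes 0.63 and 0.0814, and in control cells the median of inflammation genes turned to -0.02 and that of interferon genes to -0.00414. With normexp the inflammation median in control cells turned to -0.02 as well. Inflammation (0.706 and 0.244), interferon (0.434 and 0.0937), endothelial (0.679 and 0.746) and fibroblast lists (0.325 and 0.0937) did not pass by fry with normexp. In control cells fibroblast markers also missed with median centring (0.0874), and with quantile normalization both interferon genes (0.0922) and fibroblast markers (0.0635) missed. By camera without the block the inflammation, interferon, fibroblast and endothelial lists did not pass in either transfection.

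Division genes were lower at 72 h in both transfections, and a candidate explanation is slower division as the cultures grew denser. The change was not carried by 1 slide, where the highest within-slide median was -0.38, nor by the array scaling, where under median centring or quantile normalization the highest median was -0.42; position on the slide cannot be told apart from time, since the 4 groups formed only 4 combinations with position. Targets of YAP and TAZ, which dense cultures silence, had medians of -0.16 and -0.23 over 20 genes and a larger adjusted p = 0.155 (camera with the block; 0.381 with an estimated correlation), and quiescence and FOXO target genes had medians of 0.30 and 0.34 over 14 genes and a larger adjusted p = 0.0727 (0.135). Both explanations were to be dropped if these tests missed the threshold, but that rule was wrong, since a p above a threshold excludes nothing and the medians lie on the predicted side, so both stay open. The YAP and TAZ medians of slide 2 were on the other side (0.06 in both transfections), and in miR-214 cells the target CCDC80 rose (0.83), MYOF fell (-0.82) and the FOXO target PIK3IP1 rose (1.67). CCN2, the YAP target named above as lower in miR-214 cells, was not among the 20 genes of the list. Replication-dependent histones did not fall with the other division genes in control cells (median 0.32, 15 of 16 above 0). Their slide medians were -0.17, 0.34 and 0.51 (camera adjusted p = 0.0468, and 0.646 with an estimated correlation). In miR-214 cells the histone median was -0.17, with 9 of 16 below 0 (camera adjusted p = 0.0683).

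Other splits of the arrays were fitted with limma as well. The 10 splits of 6 arrays are too few for a share under 0.05. At 48 h the real split called 0 genes and the highest other 37, when the miR-214 arrays of replicates 1 and 2 and the control array of replicate 2 were set against the rest. At 72 h and for time in control and in miR-214 cells the real and the highest other split called 0. With both times averaged, and for the difference between both effects, 100 splits were drawn and the real split called 0. Where the real count is 0 all splits call as many by necessity (10 of 10 and 100 of 100), so these counts say nothing about chance. With both times averaged the highest called 380, with miR-214 replicates 1 and 2 and control replicate 2 together at both times, which points to a structure of the samples. For the difference between both effects the highest called 136. These splits ignore the pairing by replicate number. With the replicate block and only splits that part all 3 pairs, there were 4 splits, too few for a share under 0.05; 1 of them, the real one, reached 344 genes in control and 716 in miR-214 cells, and the highest other called 0. Those other splits put arrays of both times on each side.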
